A study of Mus musculus with 18 samples.

How the data were processed

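Whole embryonic mouse cortex at embryonic day E15.5 was measured in a conditional knockout of BAF155, a core subunit of the BAF (SWI/SNF) chromatin remodelling complex encoded by Smarcc1. Animals had received vehicle or trichostatin A (TSA), an inhibitor of histone deacetylases. The labels give 18 samples: 4 Vehicle and 4 TSA samples of RNA, 4 Vehicle and 4 TSA samples of chromatin immunoprecipitated for histone H3 acetylated at lysine 9 (H3K9ac), and 2 input samples that were not analysed here. Nothing in the labels says whether replicates were separate animals, so p-values measure only the spread between these samples. Samples without the knockout were not analysed here, so each comparison is of TSA with Vehicle within the knockout.

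The RNA files hold raw read counts per Ensembl gene, which the authors deposited with no normalization, 1 library per file. Libraries were made with a kit that does not mark strand, per the labels' protocols, so reads of overlapping and antisense genes cannot be told apart. The genome build was mm10 and SAMtools was used, per the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. Lines for unassigned reads in the deposited count files summed to 0, so the assigned share is unknown. The files list 47729 genes, of which 47224 matched a symbol, and sequences shared between near-identical genes could have been split by the counting. Total counts ranged from 6733415 to 20400727 per library. Floors of 3 counts cover counting error only, since reads carry no molecular identifiers. The intervals given are over genes or regions taken as independent, and do not cover the spread between libraries.

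The H3K9ac files are peak lists called separately for each library with MACS2 2.1.0.20140616, per the file headers, at a q-value limit of 0.1. The authors used the same input library of 18937878 tags for all 8 lists, per the file headers, although the labels list 2 inputs, and scaled the larger data set to the smaller. Tags were 50 bp long, and duplicates were reduced to 1 tag per position, per the file headers. The deposited columns are the pileup signal at each summit, the fold enrichment (a ratio to the local background) and the −log10 of the p-value and q-value. These values describe each list on its own and were used here only to rank or filter peaks within a list, so libraries were compared by the presence of a peak. Coordinates are mm10, and 1-based.

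Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries scaled by TMM, and TSA compared with Vehicle by the quasi-likelihood test with a robust prior and no covariate. Benjamini-Hochberg adjusted p-values under 0.05 over 15000 tested genes were called, and adjusted p-values below come from this test unless another is named. Log2 fold changes are TSA minus Vehicle. The standard error of a gene's change was derived from the test, as its size divided by the square root of the F statistic. Expression is in CPM (counts scaled to a common library total), computed here on TMM-scaled totals. Tests between libraries of a value other than a gene's count were two-sided exact permutation tests, whose smallest possible p with 4 against 4 is 0.0286. A gene at 0 in a whole group was compared with a floor of 3 counts over that group's summed total. No pair of replicates agreed within sampling noise, the chi-square per degree of freedom lying between 2.98 and 32.8. Each library counted once, although separate libraries of the same animal could also differ beyond sampling noise.

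Before the data were examined, 43 gene lists of cell types, pathways and complexes were fixed, holding 859 symbols, of which 4 did not occur in the files. Lists with at least 5 tested genes, without the sex-linked markers, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. That gave 41 tests, adjusted together. Camera with an estimated correlation and fry were run beside it. Counts of members that rose or fell use the adjustment over all tested genes, and counts adjusted over the list alone use the listed genes only. A list score is the median over members of the deviation of log2 CPM from each gene's mean over the 8 libraries.

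The naming rule was also fixed beforehand. It took 10 genes of interest to the study, the 10 largest called rises and 10 largest called falls among genes with mean log2 CPM above 0 whose 4 TSA libraries all lay on the same side of all 4 Vehicle libraries (without predicted genes, clones and pseudogenes), up to 4 members with the smallest p in each list, and the 5 gained and 5 lost gene windows with the smallest RNA p. Members that went against their list, genes near gained or lost regions, and genes of chromosomes 3 and 17 were named after their values were seen. Some genes that the rule takes are not reported here.

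Peaks of all 8 lists were merged into 104737 regions. A region was occupied in a library when a peak overlapped it by at least 1 bp, gained when occupied in all 4 TSA and no Vehicle libraries, and lost when the opposite held. Genes came from an NCBI RefSeq table of the same assembly that carried no strand, so the planned window around the start of transcription could not be placed. A window of 1000 bp on each side of either end of a protein-coding gene was used in its place, for 21887 genes, and is called a gene-end window. For the link to RNA, genes occupied in at least 2 more TSA than Vehicle libraries formed the gained set, and genes in at least 2 fewer the lost set. Each set was tested with camera, and its median log2 fold change was set against that of genes occupied in all 8 libraries.

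On simulated counts for 15000 genes with 200 changed, the RNA test recovered 87% of changes of 1 on the log2 scale and 38% of changes of 0.5. It called 9 unchanged genes, and 0 of 30 unmoved lists were called. Simulated genes varied independently, so this says nothing of false list calls where listed genes vary together. In the data 33.0% of tested genes were called, a far larger share than the 200 genes changed in the simulation. The adjustment of p-values depends on that share, so recovery in the data may differ from these percentages. On simulated peaks for 10038 windows, 100 of 100 gained and 100 of 100 lost windows were found. Each simulated peak lay in all 4 libraries of 1 group and none of the other. That checks the counting only, not how many real changes would be found. Alternatives covered DESeq2 1.42.0, other scaling factors, other filters on low counts, limma-voom, a replicate block, sequencing lane as a covariate, stricter peaks, equal list lengths, wider windows, other overlaps, and leaving out each library in turn. Fits with Xist status as a covariate, without the sex chromosomes, without the pair of Vehicle libraries richest in mitochondrial reads, with the trend over genomic span removed, and windows over whole genes were added after seeing the data. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.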

Results

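RNA and H3K9ac, a histone mark found at active promoters and enhancers, were profiled in cortex at embryonic day E15.5 of BAF155 conditional knockout mice given vehicle or TSA. By its title, the study asks how histone H3 acetylation bears on basal progenitors, the dividing cells outside the ventricular zone, and on Trnp1, a nuclear protein gene that regulates progenitor behaviour. RNA totals were 14216775, 15600340, 14357279 and 12200426 counts in Vehicle 1 to 4 and 6733415, 18080205, 20400727 and 16347934 counts in TSA 1 to 4. H3K9ac lists rested on 11824246 to 24075842 tags in Vehicle and 15365856 to 19920755 tags in TSA.

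Smarcc1, which encodes BAF155 (ENSMUSG00000032481, chromosome 9, 110132024 to 110240178), had 130, 148, 141 and 124 CPM in Vehicle 1 to 4 and 133, 132, 118 and 144 CPM in TSA 1 to 4. Its log2 fold change was −0.05 ± 0.09 (SE, n = 4 per group, edgeR adjusted p = 0.732). Counts per whole gene in whole cortex, with no sample that carries the intact gene, do not check the deletion, whose exons are not given in the sources used here. Smarcc2, which encodes the paralogous subunit BAF170 (chromosome 10, 128459182 to 128490591), rose by 0.47 ± 0.11 on the log2 scale, from 579 ± 76.0 to 801 ± 51.3 CPM (SD, n = 4, edgeR adjusted p = 0.00505).

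Eomes, which encodes TBR2, the transcription factor that marks basal (intermediate) progenitors, rose from 71.0 ± 18.1 CPM in Vehicle to 302 ± 23.4 CPM in TSA (SD, n = 4 each). The log2 fold change was 2.09 ± 0.15 (SE, edgeR adjusted p = 1.36e-06). Pax6, a transcription factor of apical progenitors, fell from 314 ± 54.2 to 108 ± 10.6 CPM, a log2 change of −1.54 ± 0.12 (adjusted p = 2.49e-06). Tbr1, a transcription factor gene of deep-layer neurons, rose by 0.90 ± 0.11 (adjusted p = 7.54e-05). Trnp1 had 13.3 ± 1.35 CPM in Vehicle and 14.7 ± 2.04 CPM in TSA, a log2 fold change of 0.13 ± 0.13 that did not pass (adjusted p = 0.499).

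**Figure D1:**
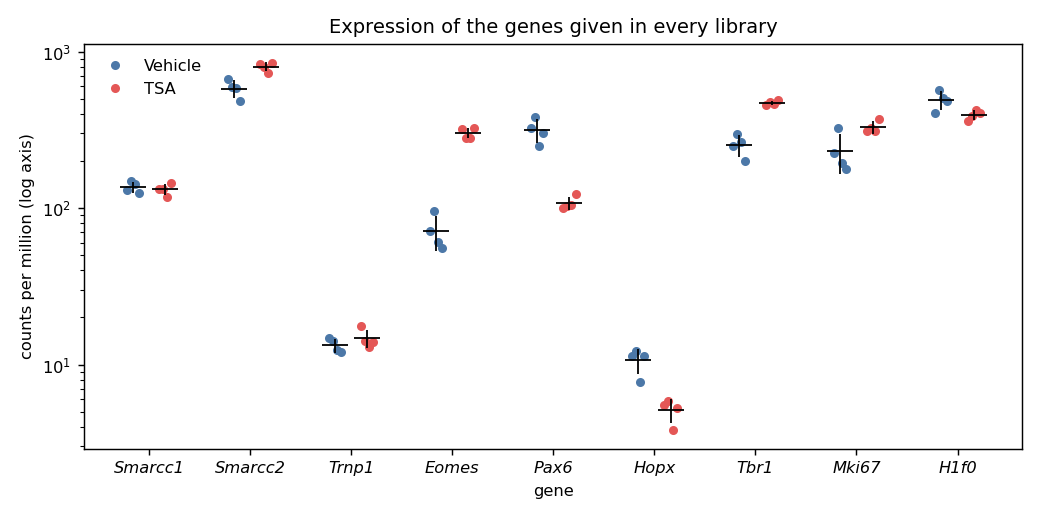
CPM (vertical log axis) of the 9 genes given in every library (horizontal axis), with 1 point per library, 4 Vehicle in blue and 4 TSA in red, and black bars for mean ± SD. All 4 TSA libraries lie above all 4 Vehicle libraries for Eomes, Tbr1 and Smarcc2 and below them for Pax6 and Hopx, while Smarcc1, Trnp1, Mki67 and H1f0 overlap.

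Other genes fixed beforehand passed with smaller margins. Hopx, a marker of basal radial glia, fell from 10.7 ± 1.97 to 5.11 ± 0.89 CPM, a log2 change of −1.08 ± 0.19 (adjusted p = 0.000689). Mki67, a proliferation marker, rose by 0.52 ± 0.16 (adjusted p = 0.0205) although the groups overlapped. H1f0, a linker histone gene that is often induced by deacetylase inhibitors, fell by 0.31 ± 0.11 on the log2 scale (adjusted p = 0.0400). Leaving out Vehicle 3, Vehicle 4 or TSA 4 ended the call of Mki67 (edgeR adjusted p = 0.0625, 0.0707 and 0.0672), as did leaving out the pair of Vehicle libraries richest in mitochondrial reads (log2 change 0.34, adjusted p = 0.202) and Xist status as a covariate (0.0790). That of H1f0 ended without Vehicle 2, 3 or 4 or TSA 1, 2 or 4 (adjusted p from 0.0588 to 0.141), with RLE factors (0.0510), with lane (0.0610) and with Xist status (0.363) as covariates, and with each library's trend over genomic span removed, a setting added after seeing the data, its log2 change was −0.08 (limma adjusted p = 0.684).

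Across the transcriptome, 2314 genes rose and 2640 fell among 15000 tested, 33.0% in all. The median size of a called change was 0.51 on the log2 scale; 184 genes rose by more than 1 and 263 had a change below −1. In 4247 called genes, all 4 TSA libraries lay on the same side of all 4 Vehicle libraries. Of all tested genes, 32.3% were separated in this way, against 2.86% by chance. Genes with clone or pseudogene names made up 260 of the calls. The first principal component held 47.8% of the variance and separated the groups.

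Among the 10 largest rises, Neurog1, a proneural factor that specifies excitatory neurons (chromosome 13, 56250478 to 56252180), rose from 0.862 ± 0.207 to 7.43 ± 0.732 CPM, a log2 change of 3.08 ± 0.23 (adjusted p = 1.36e-06). The related Neurod4 rose from 1.53 ± 0.522 to 10.2 ± 0.81 CPM (log2 change 2.72 ± 0.22, adjusted p = 3.36e-06). The smallest p belonged to Rlbp1, which encodes a retinaldehyde-binding protein (chromosome 7, 79374865 to 79392250), at 11.4 ± 1.37 CPM in Vehicle and 85.1 ± 10.3 CPM in TSA (log2 change 2.89 ± 0.12, adjusted p = 7.83e-09). Sycp1, which encodes a protein of the meiotic synaptonemal complex, had 0 counts in all 4 Vehicle libraries and 4.14 ± 1.88 CPM in TSA, at least 77.8-fold higher than a floor of 3 counts over the Vehicle group, 0.0532 CPM. The other genes in this group were Ltbp2 (4.65), Hmga1b (4.33), Slc14a1 (4.12), Dapk2 (2.78), Ccl28 (2.71) and Tac2 (2.71), with the log2 change in parentheses. Hmga1b closely resembles Hmga1, so its counts are uncertain. Ltbp2 had 1, 0, 4 and 2 counts in Vehicle 1 to 4, so its change is imprecise, and without Vehicle 3 the changes of Ltbp2 and Hmga1b were 5.38 and 5.23. Without the Vehicle libraries richest in mitochondrial reads that of Slc14a1 was 5.98.

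Among the 10 largest falls, Kirrel2, a cell adhesion gene (chromosome 7, 30447766 to 30457515), fell from 13.6 ± 3.64 to 0.688 ± 0.163 CPM, a log2 change of −4.22 ± 0.25 (adjusted p = 1.39e-07). Prdm13 and Helt, transcription factor genes tied to inhibitory neuron fate, fell by 3.73 ± 0.34 (adjusted p = 1.07e-05) and fell by 3.22 ± 0.36 (adjusted p = 4.46e-05) on the log2 scale. Crabp1, which encodes a retinoic acid binding protein, fell from 20.8 ± 2.25 to 2.83 ± 0.205 CPM (log2 change −2.86 ± 0.15, adjusted p = 4.37e-08). Wls, needed for Wnt secretion, fell from 107 ± 10.8 to 19.6 ± 5.40 CPM (log2 change −2.46 ± 0.17, adjusted p = 1.49e-06). Cdhr1 (−2.78), Nts (−2.65), Capza1 (−2.61), Ikzf1 (−2.54) and Rxrg (−2.47) completed the group, with the log2 change in parentheses. Vehicle 3 held the highest levels of Ikzf1, 18.7 CPM against 3.23 to 7.52 in the other Vehicle libraries, and of Rxrg, 35.1 CPM against 5.29 to 20.1. The call of Rxrg ended without Vehicle 4, TSA 1 or TSA 3, with adjusted p of 0.0531, 0.0506 and 0.0908, with limma-voom (0.0631), with no filter (0.0974) and with Xist status as a covariate (0.214). Without Vehicle 3 the log2 changes of Ikzf1 and Rxrg were −1.91 and −1.84, and without TSA 3 that of Prdm13 was −4.34.

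The basal progenitor list was higher in TSA, with 10 of 19 tested members risen and 2 fallen (camera adjusted p = 0.000213; adjusted p = 0.535 with an estimated correlation). Kif26b rose by 2.1 ± 0.11, Heg1 by 1.69 ± 0.10, Eomes by 2.09 ± 0.15 and Neurog1 by 3.08 ± 0.23. The members that fell were Dll3 (−0.82) and Hes6 (−0.28), a Notch ligand and a neurogenic HES-family gene. Adjusted over the list alone, the counts were again 10 and 2. In the list of basal radial glia and basal progenitor amplification, 6 of 22 rose and 1 fell (adjusted p = 0.0203; adjusted p = 0.535 with an estimated correlation). Tnc, an extracellular matrix gene, rose by 1.21 ± 0.15, Gli3, of the Hedgehog pathway, by 0.93 ± 0.17 and Hhip, of the same pathway, by 1.36 ± 0.36, and Hopx was the member that fell. Adjusted over the list alone, these counts were also 6 and 1. This second call ended in settings added after seeing the data, with the span trend removed (adjusted p = 0.0531), without the pair of Vehicle libraries richest in mitochondrial reads (0.0638) and with Xist status as a covariate (0.0880).

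Apical progenitor genes went both ways, with 13 of 28 risen and 7 fallen, 13 and 8 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.181). Aldoc, Veph1 and Sox3 rose by 1.34 ± 0.11, 1.52 ± 0.14 and 1.77 ± 0.20, and Pax6 fell. Of 29 G2/M and mitosis genes 9 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.0341; adjusted p = 0.831 with an estimated correlation). Cdk1, the mitotic kinase, fell by 0.71 ± 0.09 on the log2 scale, Birc5 by 0.80 ± 0.13 and Ttk by 0.64 ± 0.11, and the member that rose was Mki67. Of 27 G1/S and DNA replication genes, 11 fell and 1 rose, 12 and 2 adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0964). Vehicle 2 had the highest G2/M list score, 0.452, against −0.117 to 0.031 in the other Vehicle libraries, and without it the G2/M call ended (adjusted p = 0.663), as it did without TSA 1, TSA 2 or TSA 3 (0.0773, 0.0545 and 0.0763), with Xist status as a covariate (0.801) and with the span trend removed (0.0835). The G1/S list passed without Vehicle 1 (0.0451) or Vehicle 4 (0.0248), and without both, the Vehicle libraries richest in mitochondrial reads, the adjusted p were 0.00136 for G1/S and 0.000171 for G2/M.

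Genes of excitatory cortical neurons were higher. In the upper-layer list 12 of 15 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.07e-05; adjusted p = 0.535 with an estimated correlation). Unc5d, Pou3f2, Mdga1 and Dok5 rose by 1.17 ± 0.11, 0.89 ± 0.11, 0.90 ± 0.12 and 1.05 ± 0.15, and Ptn (−0.56) and Lmo4 (−0.40) fell. In the deep-layer list 9 of 16 rose and 4 fell, 11 and 4 adjusted over the list alone (adjusted p = 0.00907; adjusted p = 0.535 with an estimated correlation). Sox5 rose by 1.17 ± 0.14 and Wnt7b by 0.73 ± 0.11. Foxp2 (−1.10), Pcp4 (−0.63), Lmo3 (−0.47) and Crym (−0.57) fell. Pan-neuronal genes gave 11 rises and 2 falls among 24 (adjusted p = 0.0203; adjusted p = 0.546 with an estimated correlation), and adjusted over the list alone the same 11 and 2. Neurod2 rose by 0.82 ± 0.13 and Rbfox3 by 0.59 ± 0.09, while the microtubule regulators Stmn1 (−0.54) and Stmn2 (−0.50) fell. Of 30 synaptic transmission genes 16 rose, among them Pclo (0.75 ± 0.09) and Cacna1e (0.69 ± 0.09), and 4 fell, among them the glutamate receptor gene Gria4 (−0.83). The counts adjusted over the list alone were 16 and 4 (adjusted p = 0.00492; adjusted p = 0.535 with an estimated correlation). With the span trend removed, the pan-neuronal (adjusted p = 0.194) and synaptic (0.0776) calls ended, as they did with Xist status as a covariate (0.121 and 0.0887); the pan-neuronal call also ended without the Vehicle libraries richest in mitochondrial reads (0.102) and without genes of the sex chromosomes (0.0578).

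Markers of inhibitory neurons and their birthplace, the ganglionic eminence below the cortex, were lower. In that list 16 of 25 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.48e-05; adjusted p = 0.535 with an estimated correlation). Dlx6os1 fell by 2.04 ± 0.14 on the log2 scale, Dlx1 by 1.16 ± 0.12, Gsx2 by 2.18 ± 0.24 and the chemokine receptor gene Cxcr4 by 1.05 ± 0.11. The members that rose, Nkx2-1 (2.22 ± 0.45), Lhx8 (2.27 ± 0.62) and Lhx6 (0.51 ± 0.12), belong to the medial eminence. Striatal neuron genes fell in 9 of 15 and rose in 1, Ppp1r1b (0.91 ± 0.19), and adjusted over the list alone 10 fell and 1 rose (adjusted p = 0.00812; adjusted p = 0.608 with an estimated correlation). The neuropeptide precursor Penk fell by 2.05 ± 0.38 on the log2 scale. Striatal scores were spread over the Vehicle libraries, at −0.20, 0.133, 1.31 and 0.798 in Vehicle 1 to 4, against −1.03, −0.345, −0.481 and −0.236 in TSA 1 to 4. With Xist status as a covariate the striatal call ended (adjusted p = 0.0887).

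**Figure D2:**
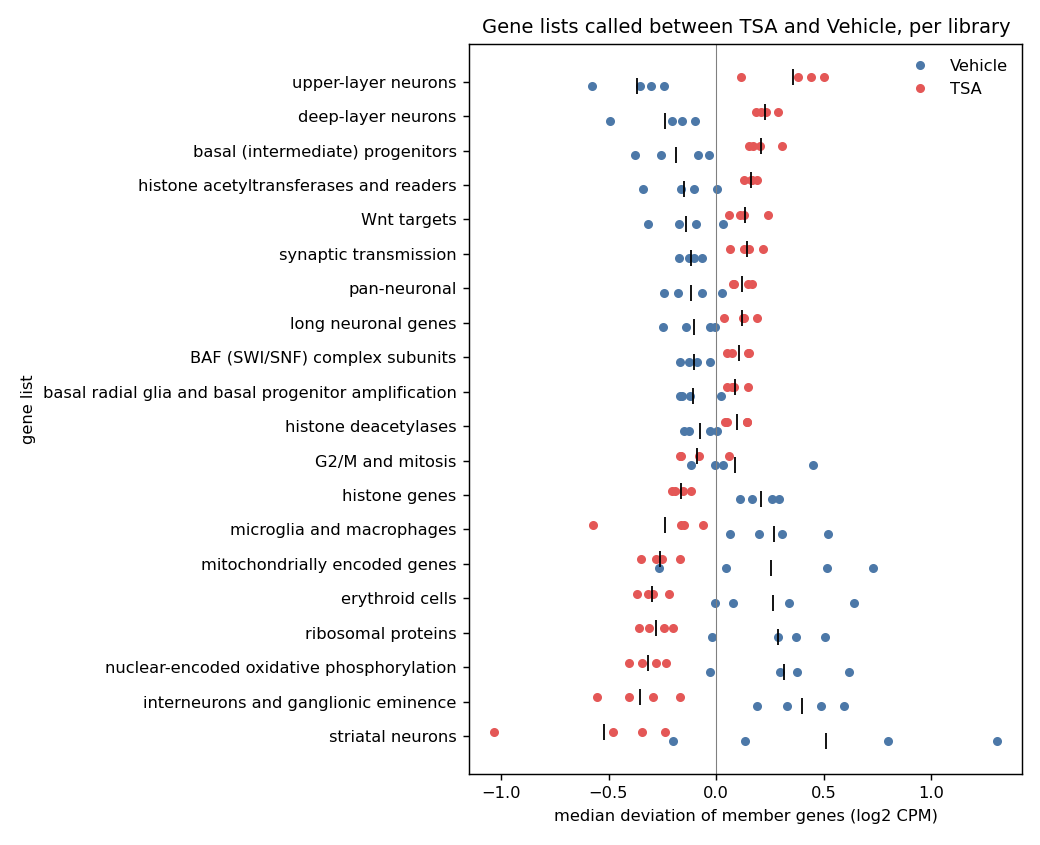
Median deviation of member genes from their mean over the 8 libraries (horizontal axis, log2 CPM) for the 20 called lists (vertical axis), with 1 point per library, 4 Vehicle in blue and 4 TSA in red, and a black tick at each group mean. Upper-layer scores run from −0.575 to −0.243 in Vehicle and 0.117 to 0.501 in TSA, whereas striatal scores run from −0.20 to 1.31 in Vehicle.

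Lists of oxidative phosphorylation, ribosomal protein and mitochondrially encoded genes were lower. In nuclear-encoded oxidative phosphorylation 36 of 42 fell and 0 rose, 37 adjusted over the list alone (camera adjusted p = 1.15e-12; adjusted p = 0.535 with an estimated correlation), with a median log2 fold change of −0.65. Uqcrh, Cox7a2 and Cox4i1, of the respiratory chain, fell by 0.99 ± 0.11, 1.05 ± 0.12 and 0.997 ± 0.127 on the log2 scale. Of 40 ribosomal protein genes 25 fell and 0 rose, 26 adjusted over the list alone (adjusted p = 1.94e-09; adjusted p = 0.535 with an estimated correlation), including Rps3 (−0.99 ± 0.13) and Rpl32 (−1.08 ± 0.14). Many pseudogenes copy ribosomal protein genes, so their single values are uncertain. Mitochondrially encoded genes fell in 6 of 9, 8 adjusted over the list alone (adjusted p = 0.0103; adjusted p = 0.608 with an estimated correlation), a call that ended without Vehicle 1 and Vehicle 4 (adjusted p = 0.160). Mitochondrial genes took 2.86, 1.6, 2.0 and 3.36% of counts in Vehicle 1 to 4 and 1.48 to 1.71% in TSA (means 2.45 ± 0.80 and 1.58 ± 0.09, exact p = 0.0571). In each library, the deviation of log2 CPM from each gene's mean over the 8 libraries was regressed on the log10 of genomic span. The slope was −0.10 ± 0.11 in Vehicle and 0.10 ± 0.05 in TSA (SD, n = 4, exact permutation p = 0.0571). These group means are equal and opposite by construction, so only their difference carries information. The median log2 fold change ran from −0.50 for genes spanning under 1 kb to 0.18 over 300 kb.

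BAF complex subunits gave 9 rises among 27 and 1 fall, 10 and 1 adjusted over the list alone (adjusted p = 0.00536; adjusted p = 0.546 with an estimated correlation). Arid1a rose by 0.69 ± 0.10, Bicra by 0.74 ± 0.14 and Dpf3 by 0.63 ± 0.12, and Actl6a (−0.48 ± 0.09) fell. Of 16 histone acetyltransferases and readers 10 rose, including Crebbp (0.63 ± 0.09) and Ep300 (0.62 ± 0.10), and 2 fell, Hat1 (−0.80) and Kat8 (−0.40); adjusted over the list alone 10 rose and 4 fell (adjusted p = 0.0189; adjusted p = 0.608 with an estimated correlation). Of 21 histone deacetylases and corepressors 8 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.0341; adjusted p = 0.535 with an estimated correlation), led by Hdac5 (0.56 ± 0.11). Histone genes fell in 8 of 16, and adjusted over the list alone 10 fell and 1 rose (adjusted p = 0.00361; adjusted p = 0.535 with an estimated correlation). H2afv, H3f3a and H2afj, which encode replication-independent histones, fell by 0.95 ± 0.10, 0.87 ± 0.12 and 0.99 ± 0.13 on the log2 scale. The histone list was not tested with the span trend removed, so its fall was not checked against that trend. The deacetylase call ended without TSA 4 (adjusted p = 0.0514), without genes of the sex chromosomes (0.0808) and with the span trend removed (0.0547), and it and the acetyltransferase call ended without the Vehicle libraries richest in mitochondrial reads (0.0516 each). Among 18 genes often induced by deacetylase inhibitors, Mt2 rose by 0.75 ± 0.19 and Clu and H1f0 fell, by 0.34 ± 0.11 and 0.31 ± 0.11 on the log2 scale (camera adjusted p = 0.977). Adjusted over the list alone, 1 rose and 0 fell.

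The remaining called lists were markers of other cells, Wnt targets and long genes. Microglial and macrophage genes fell in 8 of 20, 9 adjusted over the list alone, including Lyz2 (−1.70 ± 0.32) and Aif1 (−1.49 ± 0.34) (adjusted p = 0.00667; adjusted p = 0.535 with an estimated correlation). Erythroid genes fell in 4 of 13 on either adjustment, counting adjusted over the list alone, including Tfrc (−0.95 ± 0.09) and Hbb-bs (−1.10 ± 0.23) (adjusted p = 0.0203; adjusted p = 0.535 with an estimated correlation). Wnt targets rose in 3 of 11, Axin2, Lef1 and Nkd1, by 0.44 ± 0.12, 0.68 ± 0.22 and 0.35 ± 0.12, with the same count adjusted over the list alone (adjusted p = 0.0341; adjusted p = 0.535 with an estimated correlation). Of 26 long neuronal genes 8 rose and 3 fell, 10 and 4 adjusted over the list alone, with Auts2 risen by 0.91 ± 0.11 and Nrxn3 fallen (−0.77 ± 0.13) (adjusted p = 0.0445; adjusted p = 0.546 with an estimated correlation). With the span trend removed the direction of this list turned (adjusted p = 0.802), and its call ended without Vehicle 1 (0.153), TSA 1 (0.0621), TSA 2 (0.0651) or TSA 3 (0.126), with Xist status as a covariate (0.505), without the Vehicle libraries richest in mitochondrial reads (0.212) and without genes of the sex chromosomes (0.0522). The Wnt call ended without Vehicle 4 (0.0738) or TSA 3 (0.0763), with Xist status as a covariate (0.139), without the Vehicle libraries richest in mitochondrial reads (0.188), and with the span trend removed (0.0776), where the erythroid call ended too (0.0531).

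In all, camera called 11 lists higher and 9 lower of 41, and fry called 19. With an estimated correlation 0 were called, and 1, histone genes, had an unadjusted p under 0.05 (0.0361). In 18 lists the scores of all TSA libraries lay on the same side of all Vehicle libraries, with the exact p of 0.0286 becoming 0.0651 after adjustment over 41. Xist, transcribed from the inactive X chromosome of females, had 1788 to 3228 CPM in the Vehicle libraries and 2277 CPM in TSA 4 but 0.297, 1.44 and 0.490 CPM in TSA 1 to 3. The Y-linked Ddx3y had 37.4 to 55.1 CPM in TSA 1 to 3 and 0.122 CPM in TSA 4. With Xist status as a covariate, chosen after seeing the data, 757 genes rose and 818 fell. In that fit the calls of Smarcc2 (log2 change 0.54, edgeR adjusted p = 0.0645), Hopx (−1.0, adjusted p = 0.0626), Mki67 (0.69, adjusted p = 0.0790), H1f0 (−0.28, adjusted p = 0.363), Ikzf1 (−2.64, adjusted p = 0.105) and Rxrg (−2.23, adjusted p = 0.214) ended, while those of Eomes, Pax6 and Tbr1 did not.

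H3K9ac peaks numbered 41987, 41331, 43645 and 22668 in Vehicle 1 to 4 and 46714, 53285, 32248 and 61217 in TSA 1 to 4. The means of 37408 ± 9875 and 48366 ± 12273 (SD, n = 4) did not differ beyond the spread between libraries (exact permutation p = 0.229). Peaks covered 15.3 ± 4.91 Mb in Vehicle and 19.3 ± 5.69 Mb in TSA (exact p = 0.343). Gene-end windows with a peak numbered 11707 ± 1307 and 12372 ± 949 of 21887 (exact p = 0.486). Without TSA 3 the difference in peaks reached the smallest possible p, 0.0286. Without Vehicle 4 the difference in windows went from 665 to 14.2 and that in covered length from 3.96 to 1.58 Mb. The differences were 346 windows and 1.62 Mb without TSA 4, 1100 windows and 6.22 Mb without TSA 3, and 35.8 windows at equal list lengths. Overlap of covered bases was alike within and between groups, with mean Jaccard indices of 0.441 for Vehicle pairs, 0.418 for TSA pairs and 0.422 between them.

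**Figure D3:**
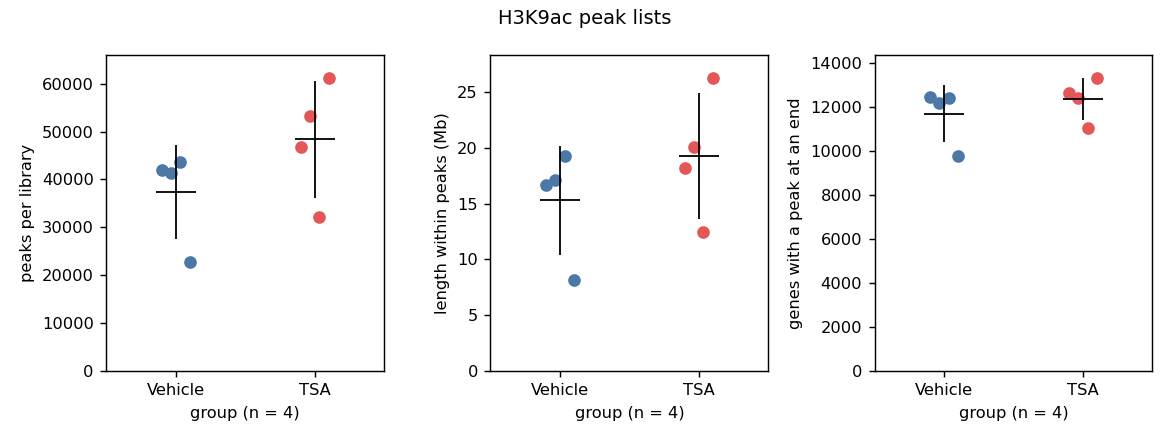
Peaks per library, length within peaks in Mb, and genes with a peak at an end (vertical axes) for the 4 Vehicle and 4 TSA H3K9ac lists (horizontal axis), with 1 point per library and black bars for mean ± SD. The groups overlap in all panels, and Vehicle 4, at 22668 peaks, lies below the other Vehicle libraries.

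By presence of peaks, 207 merged regions were gained in TSA and 21 were lost, or 71 and 51 at equal list lengths, and 12400 of 104737 were occupied in all 8 libraries. Of the gained regions 68.1% overlapped a protein-coding gene, the table used giving no exons. That share was not computed for all merged regions. A gained region lay 3993 bp from Neurog2, a proneural gene (chromosome 3, 127627493 to 127628740). A pair of lost regions lay 6402 and 5402 bp from Pax6 (chromosome 2, 105660439 to 105662494 and 105662633 to 105663494), and a gained region lay within Pax6 itself (105680662 to 105683409). Lost regions also overlapped Gsx2 (chromosome 5, 75076233 to 75077456) and Sp9 (chromosome 2, 73271955 to 73272549), genes of the ganglionic eminence. Without TSA 3 the gained regions numbered 839, and without Vehicle 4 the lost regions numbered 159.

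Among gene-end windows 9082 of 21887 were occupied in all 8 libraries, 17 were gained and 1 was lost, or 9 and 7 at equal list lengths. The genes named by the rule with gained windows were Itprid1 (RNA log2 change 1.23 ± 0.18, adjusted p = 0.000220), the splicing regulator Rbfox2 (0.36 ± 0.10, adjusted p = 0.0120), Cabp7 (0.73 ± 0.21, adjusted p = 0.0152), Cd34 (−0.50 ± 0.19, adjusted p = 0.0644) and Krt222 (−0.43 ± 0.27, adjusted p = 0.238). The lost window belonged to Tnfaip6, a hyaluronan-binding protein gene, whose RNA fell from 7.17 ± 1.35 to 2.29 ± 0.62 CPM (adjusted p = 0.000132). Trnp1 had no peak at either end in any of the 8 libraries. Pax6, Smarcc1 and Smarcc2 were occupied in all 8. Eomes was occupied in 3 Vehicle and 4 TSA libraries, Tbr1 in 2 and 4, Neurog1 in 0 and 3, and Prdm13 in 2 and 0. Cdhr1 was occupied in 0 and 3, Rxrg in 2 and 4 and Crabp1 in 1 and 2, while their RNA fell. Gained windows numbered 71 without TSA 3, and lost windows 7 without Vehicle 4.

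Whether RNA followed the mark was asked over the gene-end windows. The gained set held 759 windows, of which 448 genes were tested, and 80 rose and 42 fell. Their median log2 fold change was 0.09, against −0.01 for 8493 genes occupied in all 8 libraries, a difference of 0.10 (camera p = 0.0348; p = 0.188 with an estimated correlation). Genes occupied in all 8 libraries were also more abundant, with a median log2 CPM of 5.64 against 3.55 for the 3545 tested genes occupied in 1 to 7 libraries, and 18.1% of them rose and 21.3% fell. The genes occupied in 1 to 7 libraries, which include the gained set, had a median log2 fold change of 0.045, and the gained set was not tested against them. The lost set held 160 windows and 98 tested genes, of which 11 rose and 15 fell, with a difference of −0.01 (camera p = 0.824; p = 0.791 with an estimated correlation). The camera call of the gained set also ended without Vehicle 2, with a difference of 0.0687, or TSA 3, with 0.0727.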

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

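The sex test, the shuffles over chromosomes and the region and window splits were chosen only after their results were seen. The fits with Xist status, without the Vehicle libraries richest in mitochondrial reads, and with the span trend removed were added after seeing the data, the latter pair before their own results were seen. Samples standing apart from the other 3 of their group were sought in 90 groups of 4, and 11 were found, where chance gives about 1 in 20.

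TSA 4 had 2277 CPM of Xist, against 0.297 to 1.438 CPM in the other TSA libraries, so 3 of 4 TSA libraries and 0 of 4 Vehicle libraries lack Xist and hold Y-linked counts. A sex difference between the groups may therefore account for part of the RNA calls. With Xist status as a covariate 1518 autosomal genes were called for treatment, against 4761 without it, and 1483 were called in both with the same sign; of the 4761, 4760 kept their sign. That estimate rests on TSA 4 alone, the only TSA library with Xist, so sex and treatment cannot be told apart for these calls, those shared by both fits included. The biological explanation, treatment itself, stays open beside it.

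Nuclear-encoded oxidative phosphorylation and ribosomal protein genes were lower in TSA, with medians of −0.653 and −0.543, while short genes had lower values in general. With each library's trend over genomic span removed, the medians were −0.473 and −0.356 (differences in list score −0.472 ± 0.098 and −0.373 ± 0.06, SE), which argues against the span trend as the whole cause. Without the 2 Vehicle libraries richest in mitochondrial reads the medians were −0.463 and −0.358 (score differences −0.452 ± 0.167 and −0.413 ± 0.158, SE), so a contribution from those libraries could remain and stays open. The criterion of 2 SE around the score difference was set after these values were seen. The ribosomal medians lay between the bounds of −0.2 and −0.4 written beforehand, while both oxidative phosphorylation medians lay below −0.4. For oxidative phosphorylation, only the later criterion leaves the 2 Vehicle libraries open. An effect of TSA stays open.

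Of 96 autosomal genes called with a log2 change beyond 1.5 in size, 18 lay on chromosome 3, where 4.96 would be expected, among them Sycp1, Capza1, Wls, Neurog2, Alpk1 (2.11) and S100a10 (−2.35), and the next chromosome held 7. As many on 1 chromosome came up in a share of 0.0027 of 10000 shuffles, which argues against chance placement, although neighbouring genes are not independent. A strain segment that differs between the groups may be the source. Of the 18 genes, 16 lie between 90 and 160 Mb, 9 risen and 7 fallen. Those bounds were set for genes already known, and the share of the 699 tested genes of the chromosome inside them was not computed. The 16 genes are therefore no independent support for a segment. H3K9ac regions differing by at least 3 libraries were no more frequent inside that segment than outside, with a ratio of 0.955 (95% interval 0.695 to 1.31, an interval applied after the value was seen), which leaves a segment open. Reads shared with named pseudogene copies left 0 of the 18 genes changed by under 0.5, but only 2 of the 18 have such copies, and an effect of TSA also stays open.

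Kirrel2 had 18.95 CPM in Vehicle 2, against 11.28 to 12.4 in the other Vehicle libraries. Pax6 had 123.2 CPM in TSA 4, against 99.99 to 103.9 in the other TSA libraries. Sycp1 had 6.96 CPM in TSA 3, against 3.13 to 3.28. Capza1 had 0.91 CPM in TSA 1, against 4.44 to 4.56. Genes detected numbered 19020 in TSA 1, the library with the fewest counts, against 21960 to 22390.

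H3K9ac Vehicle 4 had 22670 peaks, against 41330 to 43640 in the other Vehicle libraries, from the largest number of tags. Its windows with a peak numbered 9755, against 12195 to 12472, and its peaks on chromosome X 261, against 793 to 812. Of its peaks, 59.52% lay in gene-end windows, against 45.49 to 47.51%. TSA 4 had 19920000 tags, against 15370000 to 16020000 in the other TSA libraries.

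The number of called genes exceeded that of every other split of the 8 RNA libraries into 4 and 4: 4954, against at most 1. So 1 of 35 splits gave as many, the smallest share that 35 splits allow. Every other split mixes TSA with Vehicle libraries, which favours few calls. The other splits therefore do not measure how many genes chance would call. For called gene lists chance cannot be excluded, since 2 of 35 splits gave at least the 20 called, the other, with Vehicle 2 and TSA 4 exchanged, calling 21. Nor can it for regions gained or lost (5 of 35 splits gave at least 228, the highest other 382) or gene-end windows (10 of 35 gave at least 18, the highest other 56). The same holds for the RNA difference of the gained set (4 of 35 gave at least 0.1013 in size, the highest other 0.1228) and the lost set (26 of 35 gave at least 0.0118, the highest other 0.0619). Every other H3K9ac split with at least 228 regions put Vehicle 4 and TSA 3, the shortest peak lists, on the same side. Those splits may therefore reflect list length, and they do not measure chance alone.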

How the results depend on the processing

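The fits with Xist status, without the sex chromosomes, without the Vehicle libraries richest in mitochondrial reads, with limma-trend and the span trend removed, and over whole gene bodies were chosen after seeing the data. The cause of each shift below was not tested. Genes higher and lower in TSA stayed within 1.5 times 2314 and 2640 in every setting but 1, ranging without 1 library from 1707 to 2702 and from 2104 to 2891; with Xist status as a covariate they were 757 and 818. Gene lists called numbered 0 with an estimated correlation, 12 with the span trend removed (39 lists tested, histone and mitochondrially encoded genes left out) and 17 to 21 without 1 library. Of the values of named genes under other settings, 611 kept their direction and call, 25 lost the call (mainly H1f0, Rxrg and Mki67) and 2 reversed, both of Smarcc1, which was never called: 0.00299 without TSA 3 and 0.0826 with Xist status. Without 1 library its lowest value was −0.0938 (without TSA 4), and its lowest in any setting −0.167, with the span trend removed.

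The RNA difference of the gained set, 0.1013, lost its call with an estimated correlation and at 2.5 kb windows (0.0793). It also lost it without Vehicle 2 (0.0687) or TSA 3 (0.0727). The call was kept at equal list lengths, where the difference was larger (0.137). It was also kept for an occupancy difference of at least 3 libraries (0.0880) or at least 1 library (0.0851). Without 1 library the RNA difference of the gained set ranged from 0.0687 to 0.129. That of the lost set, never called, ranged from −0.0466 to 0.0473 without 1 library and down to −0.118 for a difference of at least 3 libraries, and was above 0 without Vehicle 1 (0.0139), Vehicle 2 (0.0250), Vehicle 4 (0.0473) or TSA 4 (0.0430). The difference in H3K9ac peaks ranged from 6045 to 16331 without 1 library, passing only without TSA 3, and was 3522 at −log10 q of at least 5 and 2658 at a fold of at least 5. Those in covered length and windows passed in no setting run.

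Gained windows numbered 9 at −log10 q of at least 5, 7 at a fold of at least 5, 9 at equal list lengths, 175 for a difference of at least 3 libraries, and 20 to 71 without 1 library. Lost windows numbered 2 at that fold, 7 at equal lengths, 14 for at least 3 libraries, and 1 to 7 without 1 library. Gained regions numbered 74, 62, 71, 128 with 0.5 of the region covered, 1776 for at least 3 libraries, and 226 to 839 without 1 library. Lost regions numbered 9, 11, 51, 265 for at least 3 libraries, and 25 to 159 without 1 library. Leaving out a library loosens these counts by construction.

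Replicate numbers share only a number between the groups: deviations of same-numbered RNA libraries correlated at 0.0970, 0.0850, 0.0700 and 0.111, and other pairs higher in part, up to 0.155. With a replicate block 2598 genes were higher and 2744 lower, 20 lists were called, the long neuronal list no longer (adjusted p = 0.0511) and the Notch list newly so (0.0444), Rxrg lost its call (adjusted p = 0.106), the gained difference was 0.117 and the lost 0.0312, and the exact p for peaks, covered length and windows were 0.375, 0.625 and 0.625 with unchanged differences. The 6733415 counts of TSA 1 limit what can be seen of genes with few counts.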

Other observations

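The nearest-gene tests were chosen only after the regions were seen; the test of genes without peaks was set before its result. Among lists that did not pass, Notch pathway genes rose in 9 of 18 and fell in 1, with Hes1 at 0.55 and Notch3 at 0.58 risen and the ligand gene Dll3 (−0.82) fallen, the same counts adjusted over the list alone (camera adjusted p = 0.0571). Hypoxia and glycolysis genes rose in 9 of 26 and fell in 2, and adjusted over the list alone in 10 and 3 (adjusted p = 0.0914). Immediate early genes rose in 4 of 16, led by Nr4a3 (1.01), and adjusted over the list alone in 3 (adjusted p = 0.0964). Astrocyte genes rose in 5 of 11, with the gliogenic factor gene Nfia (1.04), and fell in 3, with Apoe (−1.07), and adjusted over the list alone again in 5 and 3 (adjusted p = 0.251). Imprinted genes went both ways, 6 of 24 risen and 4 fallen, 8 and 4 adjusted over the list alone, with Plagl1 (0.86) and H19 (−1.29) (adjusted p = 0.888). The Notch list passed without Vehicle 2 (0.0359) or TSA 2 (0.0199), hypoxia without Vehicle 2 (0.0388) and immediate early genes without Vehicle 3 (0.0370). With the span trend removed and with Xist status as a covariate, the Notch list passed (0.0383 and 0.0273), as did immediate early genes (0.0211 and 0.0427).

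Of other lists, given as members that rose and fell among those tested, with camera adjusted p, p53 targets had 2 and 6 of 19 (0.400), apoptosis genes 3 and 6 of 20 (0.809), integrated stress response genes 0 and 1 of 21 (0.341), heat shock genes 2 and 1 of 10 (0.981), cholesterol synthesis 2 and 3 of 20 (0.981) and interferon response 0 and 0 of 13 (0.981). Markers of endothelial cells had 0 and 2 of 18 (0.230), and passed, as lower, without Vehicle 1 (0.0331) and without the Vehicle libraries richest in mitochondrial reads (0.00152). Pericytes had 2 and 3 of 13 (0.409), meninges 1 and 2 of 15 (0.981), choroid plexus 0 and 0 of 6 (0.527), Cajal-Retzius cells 2 and 2 of 14 (0.659), the cortical hem 2 and 1 of 13 (0.659; lower with Xist status as a covariate, 0.00921) and oligodendrocyte precursors 1 and 1 of 8 (0.977). Adjusted over the list alone these counts were the same, except 2 and 1 for oligodendrocyte precursors. In the germline list, too small for a set test, Sycp1 was the only call among 3 tested genes.

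Chromosome 17 held 31 of the gained H3K9ac regions, 15% of them, and 2 of the lost, between 3081685 and 6698101. Many of these lay side by side near Tmem181a and the related genes Dynlt1a and Dynlt1b, so they are not independent of each other. Whether sequences shared between such genes account for the run was not tested. RNA of genes there, picked after their values were seen, went both ways. Among others, it fell for Dynlt1b (−0.95, edgeR adjusted p = 0.000178), Dynlt1a (−1.07, adjusted p = 0.00338) and Gtf2h5 (−0.81), rose for Tiam2 (0.62), Arid1b (0.49) and Scaf8 (0.35), and did not pass for Tmem181a (−0.20, adjusted p = 0.252). Another run of gained regions lay on chromosome 7 between 80886212 and 80911504, near Wdr73, Nmb and Sec11a. The cause of either run was not tested.

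A hypothesis formed after the regions were seen concerns the nearest gene. Its RNA may follow the gain or loss of an H3K9ac region, at any distance. No limit of distance was set, and a gained region lay 805327 bp from Pou3f3, which rose. The regions themselves numbered 228, and 5 of 35 splits of the libraries, the true split included, gave at least as many. Of 148 tested genes nearest to gained regions, 39.9% rose and 10.1% fell, against 29.7% and 10.7% of 2190 genes nearest to regions found in any other combination of 4 libraries and 16.9% and 18.5% of all 13131 tested genes (odds ratio for rising against the other regions 1.57, 95% interval 1.1 to 2.24, Fisher's exact p = 0.0123, adjusted p = 0.0246). Of 17 tested genes nearest to lost regions, 29.4% rose and 35.3% fell, against 29.7% and 10.7% near the other regions (odds ratio for falling 4.53, 95% interval 1.36 to 13.5, Fisher's exact p = 0.00697, adjusted p = 0.0246), so the nearest genes went both ways. Pax6, Gsx2, Sp9, Tnfaip6 and Ccdc77 were among those that fell, and Ank3, Siah3, Tiam2, Clasp1 and Pcnx rose. Pax6 was also nearest to a gained region and so counted in both sets. Genes near gained regions had a median span of 51.3 kb against 36.8 kb, and the trend over span was not removed, so span could account for part of the rises. Genes were treated as independent, which neighbouring genes are not. Because the hypothesis came from these same regions, the p-values are no independent support for it.

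The hypothesis that genes without H3K9ac at either end might rise more under TSA was not borne out. The median log2 change of 1093 genes with no peak in any library differed by −0.019 from that of 845 genes with similar expression and peaks in every library. The camera p of the difference was 0.956.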
